A study of Mus musculus with 24 samples.

How the data were processed

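Cortex RNA of 24 mice was measured by bulk RNA sequencing, 1 library per mouse and 6 mice in each of 4 groups. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase, enriched for poly-A RNA and prepared with the TruSeq RNA kit v2, a kit that does not mark strand. Groups were taken from each sample's genotype and treatment labels. The deposited table holds whole-number read counts per gene with no normalization, and the submitters' processing notes name STAR 2.5.2b, featureCounts 1.5.1 and the mouse build mm10. The counting options, strand setting and annotation release are not given in the sources used here. Coordinates are those of the deposited table.

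The table held 43346 genes, of which 9264 had no count in any library and 19678 passed edgeR's filterByExpr and were tested. All 37 genes of the mitochondrial chromosome were at 0 in every library, so the mitochondrial genome list could not be tested. Of the gene IDs, 97.96% were found in the GENCODE vM21 annotation, and 78.89% of those had the same start and end there. Among 112 named genes checked in that annotation, 34 had an exon overlapped by another gene; without strand such reads cannot be assigned, and the overlapped share was highest for Gm15459 (95.8%) and Gm26825 (91.8%), which overlap each other, followed by Hddc3 (76.3%), Prkag2os2 (55.5%) and Krt12 (54.4%). Values of gene families with near-identical copies (H2-Q, Tgtp, Klk1b, Cyp4a12, Trim43, Rnaset2 and Olfr genes, and ribosomal pseudogenes) are uncertain because their reads can match several copies. Total counts ran from 27933505 to 56082520 per library. The 60 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 4.61 to 68.6, so each library was counted as 1 replicate.

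Counts were scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood F-test) in R 4.3.3. A single fit over all 24 libraries gave 5 comparisons, namely induced against control within each genotype, the difference of these inductions, and R47H against WT within each treatment. Benjamini-Hochberg adjustment ran over the tested genes of each comparison, and genes at an adjusted p below 0.05 were called. Levels are given as CPM, counts relative to the TMM-scaled library total, as mean ± SD of 6 libraries. Fold changes are log2 values with the standard error (SE) of the fit. A fold against a group with no count was bounded with a floor of 3 counts over the group, and a ratio against 1 count has an exact conditional binomial 95% interval; floors and intervals cover counting error only. Trem2 and per-library measures were also compared by two-sided exact permutation tests over all 924 assignments of 6 against 6, which can reach a p of 0.00216.

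Of 36 gene lists fixed from textbook markers, 35 had at least 3 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of each comparison. They cover microglia and TREM2 signalling, interferon, antigen presentation and inflammation, lysosome and lipid metabolism, astrocytes, oligodendrocytes and their precursors, vessels, meninges, macrophages, blood, choroid plexus, neurons and synapse, neighbouring brain regions, activity and stress responses, ribosomal proteins and oxidative phosphorylation. Each test was repeated with a correlation estimated from the data, under which no list passed in any comparison, and, except for the difference of inductions, with an exact permutation test of the list's mean log2 CPM per library. Member calls are given over all tested genes and adjusted over the list alone. Genes named in the text are Trem2; the 8 largest rises and 8 largest falls among called genes with a proper symbol; the 12 called list members with the lowest p; the 10 genes with the lowest p where fewer than 8 were called; and a panel of 12 glial genes. Other members given as examples of a list, and genes named in the closing section outside this rule, were chosen after their values were seen.

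The groups, the tests, the gene lists, the rule for named genes and a first set of alternatives were chosen before the data were examined. That set held other scalings (RLE size factors, library totals), other filters on low counts, DESeq2 1.42.0, limma-voom with and without sample weights, fits on the 12 libraries compared, covariates for sex and for the oligodendrocyte list, a threshold of 0.1 and each library left out in turn. Chosen after seeing the data were covariates for the share of counts in Yam1, AY036118 and Lars2 (rRNA-like genes) and for the choroid plexus list, the removal of those 3 genes, the removal of windows rich in calls, list tests without WT_induced replicate 6, the permutation tests of list means and the averaged contrasts. The procedure was tested on simulated data for the induction in WT mice over 19509 genes. It recovered 48% of genes changed 1.2-fold, 84% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 5 of its 166 calls were false. In a simulated list test over 19512 genes the shifted list was called and 0 of the other lists were. Counts were drawn independently for each gene in these simulations. They could not show false list calls that arise from correlated genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No fit paired libraries across groups, because replicate numbers were assigned in accession order. The values of some single genes are not reported here.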

Results

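Bulk RNA sequencing was carried out on the cortex of 24 mice that carried Cx3cr1CreER, a tamoxifen-dependent Cre recombinase driven by a microglial promoter, and a TREM2 construct of either the WT or the R47H form. TREM2 is a lipid-sensing receptor of microglia, the resident macrophages of the brain, and R47H is a variant associated with the risk of Alzheimer's disease. Mice labelled induced had received tamoxifen, given to switch on TREM2 expression in microglia, and mice labelled control had received corn oil. The groups WT_control, WT_induced, R47H_control and R47H_induced held 6 mice each, 3 males and 3 females per the series text. Sex is not given per sample; 3 libraries of each group had Y-linked genes above Xist. No tamoxifen-treated group without Cre was analysed here, so tamoxifen and induction differ together. Total counts ran from 33742812 to 43961714 in WT_control, 33759496 to 46904559 in WT_induced, 31025034 to 39902640 in R47H_control and 27933505 to 56082520 in R47H_induced.

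The share of counts in 3 rRNA-like genes (Yam1, AY036118 and Lars2), a sign of library quality, averaged 15.9% ± 3.18 in WT_control, 18.3% ± 3.21 in WT_induced, 20.3% ± 2.73 in R47H_control and 17.04% ± 1.69 in R47H_induced (SD, n = 6). It was higher in R47H_control than in WT_control by 4.43 points (exact permutation p = 0.0303) and lower in R47H_induced than in R47H_control, with a difference of -3.29 points (exact permutation p = 0.0281). WT_induced replicate 6 stood apart from the other 5 libraries of its group in immune genes, and values without it are given for Trem2, for gene lists and for a choice of immune genes.

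Mouse Trem2 (chromosome 17, 48346401 to 48354147, mm10) was the gene targeted by name. Its level was 6.40 ± 0.37 CPM in WT_control, 6.61 ± 1.43 in WT_induced, 7.89 ± 0.97 in R47H_control and 6.62 ± 0.53 in R47H_induced (SD, n = 6), and the highest library was WT_induced replicate 6 at 9.32 CPM. The log2 difference of induced from control was 0.05 (SE 0.10) in WT mice and -0.25 (SE 0.10) in R47H mice, and the difference of these 2 values was -0.30 (SE 0.14); none passed after adjustment over all genes (edgeR adjusted p = 0.955, 0.945 and 0.623). Exact permutation tests of Trem2 alone gave p = 0.900 in WT and 0.0195 in R47H mice. R47H against WT gave 0.00 (SE 0.10) in induced mice and 0.30 (SE 0.10) in control mice, the latter with an edgeR adjusted p of 0.0726 and an exact permutation p of 0.0108 for Trem2 alone (0.885 in induced mice). Without WT_induced replicate 6 the induction in WT mice was -0.08 (SE 0.08), the difference of inductions -0.17 (SE 0.11) and R47H against WT in induced mice 0.13 (SE 0.08). None of these passed (lowest adjusted p = 0.423, in induced mice). In a fit on the 12 control libraries the same difference passed, at 0.30 with an adjusted p of 0.0302. With the rRNA-like share as a covariate it was 0.25 (SE 0.12, adjusted p = 0.334). The R47H_control libraries enter both this comparison and the induction in R47H mice, so the results are not independent. The origin of the TREM2 constructs is not given in the sources used here, and reads of a construct of another species need not count towards mouse Trem2, so these values do not check the labels.

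**Figure D1:**
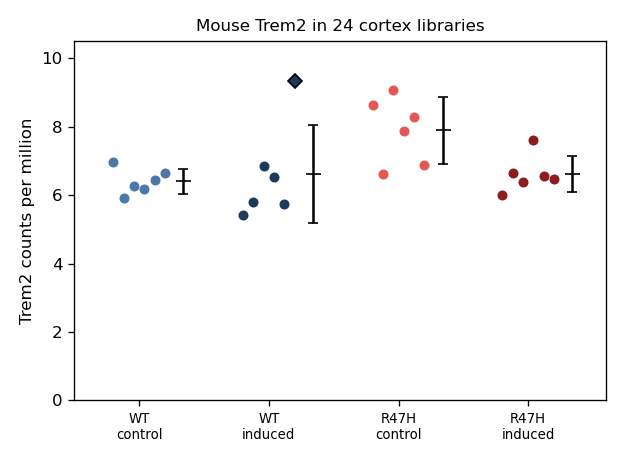
Mouse Trem2 in CPM (y axis) for each of the 24 libraries by group (x axis); points are libraries, the diamond is WT_induced replicate 6, and the bars beside the points are mean ± SD (n = 6). R47H_control averaged 7.89 CPM and the other groups 6.40 to 6.62 CPM.

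In WT mice, genes of the interferon response, which antiviral signalling turns on, were higher on average in induced than in control cortex. All 21 tested members had positive log2 fold changes, with a median of 0.93, and 19 passed when adjusted over the list alone; Ifi44 was at 1.61 (SE 0.49). Antigen presentation genes, which load and display peptides, showed the same sign in all 17 tested members (median 1.37, 15 passing when adjusted over the list alone), with Cd74, the chaperone of MHC class II, at 3.08 (SE 0.80) and H2-K1 of class I at 1.37 (SE 0.42). Without WT_induced replicate 6 the medians of the 2 lists were 0.30 and 0.36, and 0 members of either passed when adjusted over the list alone. No single gene passed over all 19678 genes in edgeR (lowest adjusted p = 0.206), where 1545 had an unadjusted p below 0.05 and chance gives 983.9. DESeq2 called 2 genes, Pdzd2 and Gm6685, and limma-voom 0.

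The camera test called 17 of 35 lists. Interferon response (adjusted p = 5.12e-13) and antigen presentation (1.17e-12) were followed upwards by reactive astrocyte (18 of 22 members positive, 2.44e-06), pan-microglial and myeloid (19 of 22, 2.71e-06), disease-associated microglia (21 of 24, 2.71e-06), astrocyte (18 of 18, 2.71e-06), ribosomal protein (65 of 83, 0.0001), thalamus (16 of 16, 0.000526), lysosome (18 of 22, 0.00116), inflammatory cytokines and receptors (11 of 12, 0.00213), endothelial (0.00912), TREM2 signalling partners (0.0157), inhibitory neuron (0.0193) and oligodendrocyte precursor (0.0378). Immediate early genes (4 of 23 positive, 0.0193), red blood cell (0 of 7 positive, 0.0223) and excitatory neuron (0.0223) were called downwards. With an estimated correlation none of the 17 passed (adjusted p = 0.295 to 0.653). Exact permutation tests of the list means gave p = 0.136 for interferon response, 0.134 for antigen presentation, 0.236 for reactive astrocyte and 0.390 for pan-microglial genes. The lowest adjusted p over the lists was 0.303, for lysosome. Adjusted over the list alone, 1 reactive astrocyte and 1 inflammatory gene passed beside the interferon and antigen presentation genes, and in lists not called 1 Trem family gene, 1 blood leukocyte gene and 1 border-associated macrophage gene. Gfap, the astrocyte filament protein, was at 137 ± 64.7 CPM in WT_induced and 102 ± 10.2 in WT_control (log2 0.44, SE 0.18), and C4b, a complement component, at a log2 value of 0.99 (SE 0.32). Of the panel, the microglial genes Tyrobp (0.28, SE 0.16), Aif1 (0.30, SE 0.19), Tmem119 (0.17), Csf1r (0.03), P2ry12 (-0.07) and Cx3cr1 (-0.04) did not pass, nor did Apoe (0.12, SE 0.06) or Itgax (2.09, SE 0.72).

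Genes with the lowest p in this comparison were Pdzd2 (0.20, SE 0.04), Gm6685 (1.26, SE 0.25), Gm10557 (-0.52, SE 0.11), Prkag2os2 (-0.50), Pcdh17 (0.13, SE 0.03), Scg2 (0.17, SE 0.04), Cckbr (-0.17), P2ry1 (0.31, SE 0.07), B3galnt2 (-0.20) and Gm26413 (-0.86). Scg2 encodes secretogranin II of neuronal granules, Pcdh17 a protocadherin and P2ry1 a purine receptor; none passed. The disease-associated genes Cst7 and Clec7a were below the filter: Cst7 had 211 counts in all, 34 of them in WT_induced replicate 6, and the 2 gene IDs of Clec7a had 183 and 42, with 69 and 12 in that library. Without replicate 6 the median was 0.30 for interferon response and 0.36 for antigen presentation, both lists still passed camera (adjusted p = 1.40e-05 and 3.62e-07), and 0 of their members passed when adjusted over the list alone. The calls of pan-microglial (adjusted p = 0.918), TREM2 signalling partners (0.742), inflammatory (0.554) and red blood cell lists (0.0910) were lost without it. Homeostatic microglia (adjusted p = 0.00462) and cholesterol synthesis (0.0248) were then called downwards. Without replicate 6 Ifi44 was at 0.96 (SE 0.41), Cd74 at 0.72 (SE 0.28), H2-K1 at 0.46 (SE 0.20) and C4b at 0.33 (SE 0.12). Of the panel, Gfap was then at 0.13, Itgax 0.33, Tyrobp 0.01, Aif1 -0.03 and Csf1r -0.06.

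**Figure D2:**
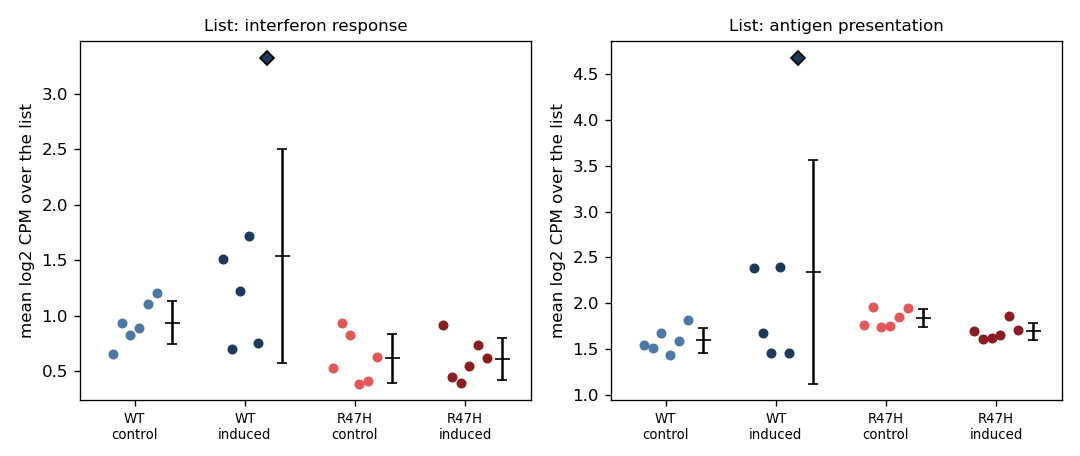
Mean log2 CPM over the interferon response list (left) and the antigen presentation list (right) for each of the 24 libraries by group; points are libraries, the diamond is WT_induced replicate 6, and the bars are mean ± SD (n = 6). Replicate 6 lies at 3.32 and 4.68, against group means of 0.94 and 1.59 in WT_control.

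In R47H mice, immediate early genes, which neuronal activity turns on, were higher in induced than in control cortex. Of 23 tested members 21 had positive log2 fold changes (median 0.31), among them Nr4a1 at 0.65 (SE 0.32) and Arc at 0.59 (SE 0.38), and 2 passed when adjusted over the list alone. Glucocorticoid response genes (14 of 17 positive, median 0.15) and circadian clock genes (13 of 16) were also higher, with Sgk1, a steroid-induced kinase, at 0.46 (SE 0.11) and the clock gene Per1 at 0.40 (SE 0.10). Homeostatic microglial genes were lower, with 5 of 19 positive and a median of -0.14; P2ry12, a purine receptor of resting microglia, was at 34.9 ± 1.55 CPM in R47H_control and 30.1 ± 3.88 in R47H_induced (log2 -0.22, SE 0.06), and Cx3cr1, the fractalkine receptor, at 20.3 ± 0.724 and 17.4 ± 0.877 (log2 -0.22, SE 0.07). With the rRNA-like share as a covariate P2ry12 was at -0.21 (SE 0.07) and Cx3cr1 at -0.13 (SE 0.07). Over all 19678 genes 0 passed in edgeR (lowest adjusted p = 0.429), with 1006 at an unadjusted p below 0.05; DESeq2 called 2, Stmn1 and Hmgn2, limma-voom 0, and edgeR on the 12 libraries 1.

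Camera called 11 lists here. Upward calls were immediate early genes (adjusted p = 2.06e-12), glucocorticoid response (5.59e-07), circadian clock (6.72e-07) and cholesterol synthesis (18 of 23 positive, 0.000413). Downward calls were meningeal fibroblast (1 of 17 positive, median -0.15, 2.72e-07), homeostatic microglia (1.62e-06), pan-microglial and myeloid (3 of 22 positive, 0.00392), border-associated macrophage (median -0.14, 0.00527), reactive astrocyte (median -0.11, 0.0113), mural cell (0.0145) and inhibitory neuron (0.0203). With an estimated correlation none passed (adjusted p = 0.103 to 0.832). Exact permutation tests of the list means gave p = 0.00216 for homeostatic microglia, 0.00649 for pan-microglial, 0.0152 for circadian clock and 0.0844 for immediate early genes; the lowest adjusted p over the 35 lists was 0.0758. Interferon response (median -0.03, adjusted p = 0.849), antigen presentation (-0.10, 0.371), disease-associated microglia (0.229), TREM2 signalling partners (0.462) and lysosome (0.189) did not pass. With WT_induced replicate 6 left out of the shared fit, antigen presentation (0.0190) and lysosome (0.0450) were called downwards. The rRNA-like share fell between the same groups. Adjusted over the list alone, 2 homeostatic genes and 1 border-associated macrophage gene fell, and 2 circadian, 1 glucocorticoid, 1 cholesterol and 1 heat shock gene rose.

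Stmn1, which encodes the microtubule regulator stathmin (chromosome 4, 134468320 to 134473843), had the lowest p, at 106 ± 11.8 CPM in R47H_control and 76.7 ± 10.9 in R47H_induced (log2 -0.47, SE 0.09). Among the next lowest p values were those of Sfn (-1.07, SE 0.22), Map3k6 (-0.69, SE 0.16), Hmgn2 (-0.53, SE 0.12), Sepn1 (0.24, SE 0.06), Siah2 (0.21), Etv6 (-0.19), Gm9816 (0.26) and Stab1 (-0.32, SE 0.08), none of which passed. Stmn1, Sfn, Map3k6, Hmgn2 and Sepn1 all lie between 133240818 and 134552166 of chromosome 4, so their values need not be separate responses to induction. Without R47H_induced replicate 3, Stmn1 (adjusted p = 0.0022) and Hmgn2 (0.0217) passed. Of the panel, Tmem119 (-0.14), Csf1r (-0.09), Tyrobp (-0.02), Aif1 (0.03), Apoe (-0.05), Itgax (-0.44) and Gfap (-0.10) did not pass either.

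The 2 inductions were compared directly to ask whether the R47H form changed the response. Antigen presentation (0 of 17 members positive, median -1.41) and interferon response genes (median -0.94) had lower induction values in R47H than in WT mice, and immediate early genes higher ones (23 of 23 positive, median 0.47). Cd74 was at -3.58 (SE 1.13), Psmb8, an immunoproteasome subunit, at -1.78 (SE 0.68), Nr4a1 at 0.91 (SE 0.45) and Per1 at 0.53 (SE 0.15). Without WT_induced replicate 6 Cd74 was at -1.22 (SE 0.38), Psmb8 at -0.75 (SE 0.28), Nr4a1 at 1.08 and Per1 at 0.51. No gene passed over all genes in edgeR (lowest adjusted p = 0.303; 1562 at an unadjusted p below 0.05); DESeq2 called 3, Glra1, Gm10557 and Pcdh17, and limma-voom 0. Adjusted over the list alone, 4 antigen presentation genes and 1 meningeal gene were lower, and 2 circadian, 1 immediate early, 1 cholesterol and 1 excitatory neuron gene were higher.

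Camera called 17 lists for this difference. Upward calls were immediate early genes (adjusted p = 9.80e-10), circadian clock (1.60e-05) and cholesterol synthesis (0.00184). Downward calls were antigen presentation (4.24e-09), pan-microglial (1.57e-07), interferon response (1.57e-07), reactive astrocyte (2.14e-07), disease-associated microglia (2.18e-05), meningeal fibroblast (0.000831), lysosome (0.000867), inhibitory neuron (0.00118), homeostatic microglia (0.00364), astrocyte (0.00364), endothelial (0.0038), thalamus (0.019), TREM2 signalling partners (0.02) and inflammatory genes (0.0263). With an estimated correlation the adjusted p ran from 0.272 to 0.532 and none passed. Without WT_induced replicate 6 the medians were -0.31 for interferon response and -0.50 for antigen presentation, 2 antigen presentation genes passed when adjusted over the list alone, and TREM2 signalling partners (adjusted p = 0.360), homeostatic microglia (0.157) and inflammatory genes (0.494) lost their calls. The excitatory neuron list was then called upwards (0.0447). Among the lowest p values were those of Glra1, a glycine receptor subunit (-1.15, SE 0.23), Gm10557 (0.80, SE 0.16), Pcdh17 (-0.19, SE 0.04), Gm6685 (-1.55), Hecw2 (0.28), 2610005L07Rik (0.87), Gm26516 (1.32), Chn1os3 (0.31) and Diablo (0.58). Panel values were Tyrobp -0.31, Cx3cr1 -0.18, Aif1 -0.27, Csf1r -0.12, P2ry12 -0.15, Tmem119 -0.30, Apoe -0.18, Itgax -2.53 and Gfap -0.54, none passing. Without replicate 6 Tyrobp was at -0.03, Aif1 0.05, Itgax -0.77 and Gfap -0.23. With the rRNA-like share as a covariate they were at -0.07, -0.03, -1.05 and -0.21, and Cx3cr1 at -0.02. Across all tested genes the log2 fold changes of the inductions had a Pearson r of -0.15 and a Spearman rho of -0.11, where genes are not independent replicates; r ran from -0.20 to -0.05 with 1 library left out (jackknife SD 0.157).

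Between the genotypes, induced R47H cortex had lower interferon response and antigen presentation genes than induced WT cortex. Of 21 interferon genes 11 fell (20 when adjusted over the list alone), among them Irf7, a master regulator of the response (log2 -2.03, SE 0.50), Ifit1 (-1.48, SE 0.36) and Usp18 (-1.77, SE 0.46). Of 17 antigen presentation genes 7 fell (14 over the list alone), including Cd74 (-2.74, SE 0.78), H2-K1 (-1.71, SE 0.43) and Nlrc5, the activator of MHC class I genes (-2.57, SE 0.61). Without WT_induced replicate 6 these genes were closer to 0, Irf7 at -1.14 (SE 0.32), Ifit1 at -0.97 (SE 0.27), Usp18 at -0.94 (SE 0.28), H2-K1 at -0.80 (SE 0.20) and Nlrc5 at -1.36 (SE 0.34), and Cd74 did not pass (-0.37, SE 0.27, adjusted p = 0.514). Striatal marker genes fell in 4 of 16 cases (9 over the list alone), among them Pde10a, a phosphodiesterase of medium spiny neurons (330 ± 14.6 CPM in WT, 280 ± 11.4 in R47H), Penk, the enkephalin precursor (242 ± 3.94 and 198 ± 19.9), and the sodium channel subunit Scn4b (326 ± 27.7 and 267 ± 19.3). These striatal genes mark a neighbouring brain region. How much of that region each sample held was not tested. Chac1, which degrades glutathione and is a target of ATF4, fell from 6.94 ± 1.03 to 4.56 ± 0.497 CPM, and Bdnf, a neurotrophin, from 23.1 ± 2.7 to 16.8 ± 1.06 CPM. In all, 509 genes were higher and 633 lower in R47H, and 146 of them differed over 2-fold.

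Rises in induced mice were led by Klk1b22, a kallikrein-related protease gene (chromosome 7, 44112673 to 44116922), with 363 counts in R47H_induced and 0 in WT_induced, at least 116-fold higher (edgeR adjusted p = 0.00229). Guca1b, a guanylate cyclase activator of photoreceptors (chromosome 17, 47385393 to 47392967), had 73 counts against 1, a ratio of 70.3 (95% interval 12.2 to 2812), and Trim43b 60 against 1 (57.7, 9.98 to 2318). Gpr15 (3.04, SE 0.38), Trim63 (2.03, SE 0.32), Gpr111 (1.99, SE 0.26), Cyp4a12b (1.84, SE 0.37) and Rnaset2b (1.75, SE 0.23) also rose. The largest falls were H2-Q7 (-4.63, SE 0.86), H2-Q6 (-4.45, SE 0.92), Tgtp2 (-3.13, SE 0.77), Ifi204 (-3.06, SE 0.75), Iigp1 (-2.99, SE 0.68), Prss41 (-2.95, SE 0.66), Gbp4 (-2.87, SE 0.62) and Tgtp1 (-2.81, SE 0.63). All of these but the protease gene Prss41 belong to interferon-induced families or MHC class I. Their WT_induced levels rested in part on replicate 6: Iigp1 was at 30.6 CPM there, 10.2 in replicate 1, 3.73 in replicate 4 and 0.90 to 1.49 in the other 3. Without replicate 6 their log2 values were -1.36 (Ifi204) to -3.01 (H2-Q7), and Tgtp2 no longer passed (-2.21, adjusted p = 0.0638). Under limma-voom the same 7 genes did not pass (adjusted p = 0.0584 to 0.286), with smaller log2 values, from -1.84 (Iigp1) to -3.31 (H2-Q7). In a fit on the 12 induced libraries H2-Q7 (0.0601), H2-Q6 (0.0791), Tgtp1 (0.0900), Gbp4 (0.0962) and Iigp1 (0.112) did not pass, with log2 values about as large. With the rRNA-like share as a covariate Tgtp2 (-2.34, SE 0.78, adjusted p = 0.0894), Iigp1 (-2.03, SE 0.62, 0.0619) and Ifi204 (-2.21, SE 0.66, 0.0544) did not pass. Nor did Tgtp2 (-2.45, 0.0528) and Iigp1 (-2.37, 0.0508) with the oligodendrocyte covariate, or Tgtp2 (-2.89, 0.0532) and Ifi204 (-2.42, 0.0676) with the choroid plexus covariate. The other called list members with the lowest p were Rgs5 of pericytes (-0.40, SE 0.07), the ribosomal protein gene Rpl10 (0.18, SE 0.03), Shank2 (-0.21, SE 0.04), Npy (-0.28, SE 0.06), Neurod2 (0.24, SE 0.05), Cox8a (0.15, SE 0.03) and Ly6a (-0.85, SE 0.19). Ly6a did not pass in the fit on 12 libraries (adjusted p = 0.0965), nor Shank2 with library totals (0.0522). Of the genes that fell, H2-Q6, H2-Q7, H2-K1 and Prss41 (from 35424850, 35439155, 33996017 and 23836785) lie on chromosome 17. Ifi204 (from 173747293) lies on chromosome 1. The 10 Mb windows of Prss41 and Ifi204 were enriched for calls in both states. H2-Q7 was at 0.578 ± 0.241 CPM in WT_control and 0.257 ± 0.0686 in R47H_control, without tamoxifen. For these genes a difference between the lines cannot be told apart from a response to induction.

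Camera called 12 lists in induced mice. Downward calls were interferon response (median -1.27, adjusted p = 1.11e-11), striatum (-0.14, 1.70e-07), antigen presentation (-1.60, 0.000113), pan-microglial (-0.32, 0.000145), heat shock and unfolded protein response (-0.12, 0.000172), endothelial (-0.13, 0.000437), synapse (0.0101), reactive astrocyte (-0.28, 0.0122), disease-associated microglia (0.0386), inflammatory (-0.31, 0.0386) and lysosome (0.0386). The choroid plexus and ependyma list was called upwards (16 of 18 positive, median 0.51, 0.0186), with 0 members called and Ttr, its most abundant gene, from 5.14 to 565 CPM over the 24 libraries. With an estimated correlation none of the 12 passed (adjusted p = 0.568 to 0.693). Exact permutation tests of the list means gave p = 0.0152 for interferon response and for striatum, 0.00433 for synapse and 0.175 for antigen presentation, with a lowest adjusted p of 0.106 over the lists. Fallen members were Ly86 (-0.65, SE 0.18) and Cd33 (-0.51, SE 0.15) of the pan-microglial list, Chac1 and Atf4 (-0.19, SE 0.05) of the stress list, Ly6a of the endothelial list, Gbp2 (-2.44, SE 0.61) of the reactive astrocyte list, B2m (-1.23, SE 0.33) of the disease-associated list, Ptgs2 (-0.47, SE 0.12) of the inflammatory list and Grn (-0.25, SE 0.06) of the lysosome list; members of the synapse list that fell included Shank2, Grin2b (-0.23, SE 0.05) and Unc13a. Without WT_induced replicate 6 Cd33 (-0.27, SE 0.10, adjusted p = 0.105), Ly86 (-0.45, SE 0.15, 0.0947), Gbp2 (-1.27, SE 0.40, 0.0798), Ptgs2 (-0.36, SE 0.11, 0.0603) and Crh (-0.38, SE 0.12, 0.0567) did not pass. B2m passed at -0.59 (SE 0.15) and Grn at -0.16 (SE 0.04). Among lists that did not pass, the inhibitory neuron list (adjusted p = 0.0608) had 3 falls, the neuropeptide genes Npy and Crh (-0.42, SE 0.11) and Crhbp, whose product binds CRH (-0.27, SE 0.07), the glucocorticoid list (0.163) 2 rises, Sgk1 (0.44, SE 0.11) and Arrdc2 (0.44, SE 0.11), and oxidative phosphorylation (0.0911) 4 rises. None of the panel genes given here passed: Itgax was at -1.79 (SE 0.70), Tyrobp -0.17, Aif1 -0.17, Csf1r -0.10, Tmem119 -0.08, Cx3cr1 -0.05, Gfap -0.03, P2ry12 0.05 and Apoe 0.08. Without replicate 6 Itgax was at -0.03, Tyrobp 0.10, Aif1 0.16 and Gfap 0.27 (adjusted p = 0.0543).

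For R47H against WT, induced, 963 genes were called without WT_induced replicate 6 (450 up, 513 down). Interferon response then had 7 members called (16 over the list alone, median -0.60, adjusted p = 1.33e-10), and antigen presentation 2 (5 down and 1 up over the list alone, median -0.16, adjusted p = 0.0565). The lists pan-microglial (0.186), disease-associated microglia (0.345), inflammatory (0.545), lysosome (0.0815), reactive astrocyte (0.306) and choroid plexus (0.0762) lost their calls, whereas striatum, synapse, heat shock and endothelial lists kept theirs. The Trem family (0.0370) and cholesterol synthesis lists (0.0472) were then called upwards. Scaling by library totals gave 507 up and 288 down, 63.8% upward against 44.6% with TMM. DESeq2 called 1494 genes and limma-voom 1095.

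In control mice, which had received no tamoxifen, striatal genes, which mark a neighbouring region, were again lower in R47H than in WT cortex samples. Of 16 striatal genes 7 fell (10 over the list alone), among them the dopamine receptor Drd2 (-0.20, SE 0.06), the signalling regulator Rgs9 (-0.28, SE 0.07) and Scn4b (338 ± 21.7 CPM in WT, 268 ± 27.5 in R47H). Immediate early genes were lower in 23 of 23 cases (median -0.39). Bdnf fell from 20.9 ± 2.92 to 15.1 ± 1.64 CPM, and 3 genes of this list fell when adjusted over the list alone. The same R47H_control libraries enter the induction in R47H mice, so the results on this list there and here are not independent. That holds for every gene and list given in both comparisons, such as Trem2, P2ry12 and the meningeal fibroblast list. The mean log2 CPM of the meningeal list was 3.53 in R47H_control, 3.38 in WT_control, 3.39 in WT_induced and 3.39 in R47H_induced. Of the synapse list 5 genes fell (Dlg4, Shank2, Grin1, Gria3 and Unc13a), and Chac1 (6.32 ± 0.44 to 4.20 ± 0.374 CPM) and its regulator Atf4 (83.6 ± 7.71 to 66.9 ± 4.35) fell in the stress list. Apoe, the main lipid carrier of the brain, rose from 812 ± 74.5 to 970 ± 63.9 CPM (log2 0.26, SE 0.06, edgeR adjusted p = 0.0126), and Igf1, a growth factor, from 12.4 ± 1.02 to 16.1 ± 1.57 CPM. In all, 530 genes were higher and 599 lower, 102 of them over 2-fold.

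Of these genes, Klk1b22 had 230 counts in R47H_control and 1 in WT_control, a ratio of 269 (95% interval 47.8 to 10676), and Guca1b 50 against 0, at least 19.5-fold higher (edgeR adjusted p = 5.77e-05). Klk1b22 did not pass under limma-voom (adjusted p = 0.0644; 0.0835 with sample weights), nor did Igsf23 (0.0687; 0.0956). Gpr15 (2.71, SE 0.37), Igsf23 (1.95, SE 0.55), Fam167b (1.77, SE 0.52), Rplp0-ps1 (1.76, SE 0.48), Cyp4a12b (1.69, SE 0.37) and Treml2 (1.65, SE 0.49), a Trem family gene beside Trem2 at 48300038 to 48312534, also rose. Falls were led by Prss41 (-2.59, SE 0.67), Rpl15-ps2 (-2.50, SE 0.72), Npw (-2.20, SE 0.53), Olfr31 (-2.12, SE 0.41), the chemokine receptor Ccr6 (-2.11, SE 0.41), the formyl peptide receptor Fpr2 (-2.09, SE 0.42), Tagap (-1.84, SE 0.37) and the MHC class I gene H2-Bl (-1.70, SE 0.23). With 1 of the 12 control libraries left out in turn, the calls of Rpl15-ps2 ended in 10 cases (adjusted p up to 0.0856), Treml2 in 9 (0.105), Fam167b in 8 (0.112), Igsf23 in 7 (0.0808), Rplp0-ps1 in 6 (0.0664) and Prss41 in 4 (0.0577). With no filter on low counts the first 5 of these did not pass (0.0656 to 0.0920). In the fits that ended a call the log2 values stayed about as large. With 1 library left out they were -2.21 to -2.56 for Rpl15-ps2 and 1.44 to 1.71 for Treml2. With values about as large, Fam167b (1.73, 0.0784) and Rplp0-ps1 (1.64, 0.0633) did not pass with the choroid plexus covariate, nor Prss41 (-2.60, 0.0575) in the fit on 12 libraries. Other list members with the lowest p were the respiratory chain genes Atp5j2 (0.28, SE 0.04) and Ndufa8 (0.16, SE 0.03), the ribosomal genes Rps15 (0.17, SE 0.03) and Rps14 (0.16, SE 0.04), Nrgn, a postsynaptic calmodulin-binding protein (-0.24, SE 0.04), Unc13a (-0.19, SE 0.04) and Pde10a (-0.18, SE 0.04). Panel values that did not pass were P2ry12 0.20 (SE 0.06, adjusted p = 0.0513), Gfap 0.51 (SE 0.18), Tmem119 0.22, Cx3cr1 0.14, Tyrobp 0.14, Aif1 0.11, Csf1r 0.01 and Itgax 0.75. In the fit on the 12 control libraries Gfap (adjusted p = 0.000640), P2ry12 (0.00962) and Tmem119 (0.0429) passed. Gfap also passed with voom sample weights (0.0268) and the oligodendrocyte covariate (0.0385). P2ry12 also passed with voom sample weights (0.0150), in DESeq2 (0.0300), without WT_control replicate 3 (0.0462), with a filter at 1 CPM (0.0477) and without the rRNA-like genes (0.0483). With the rRNA-like share as a covariate, Gfap was at 0.29 (SE 0.19, adjusted p = 0.557), Tmem119 at 0.10 (SE 0.12, 0.780) and P2ry12 at 0.20 (SE 0.08, 0.198).

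Camera called 8 lists in control mice, striatum (median -0.16, adjusted p = 1.05e-06), immediate early genes (1.05e-06), synapse (-0.06, 0.00269) and heat shock (-0.07, 0.0128) downwards, and choroid plexus (16 of 18 positive, median 0.60, 0.000809), meningeal fibroblast (16 of 17 positive, median 0.17, 0.00342), ribosomal protein (6 members up, 0.00448) and oxidative phosphorylation (6 up and 1 down, 0.0448) upwards. With an estimated correlation none passed (adjusted p = 0.713 to 0.852). The exact permutation p of the list means was 0.0152 for striatum, 0.00649 for synapse and 0.0498 for immediate early genes, with a lowest adjusted p of 0.0758 over the lists. Adjusted over the list alone, 7 ribosomal genes rose and 1 fell, 9 respiratory genes rose and 3 fell, and 0 choroid or meningeal genes passed. Interferon response had a median of -0.28 (adjusted p = 0.0838; 0.00341 without WT_induced replicate 6), the Trem family list and the lipid efflux list an adjusted p of 0.0838, and antigen presentation 0.314 (0.0181 upwards without that library), with H2-M3 rising (0.76, SE 0.20). Disease-associated microglia genes Apoe, Timp2 (0.13, SE 0.04) and Igf1 rose while the list did not pass (0.148). Crhbp (-0.28, SE 0.07) of the inhibitory neuron list (0.379) and Nrgn and the upper-layer factor Cux2 (-0.18, SE 0.05) of the excitatory neuron list (0.0831) fell. The rRNA-like share differed between the same groups, and with it as a covariate R47H against WT, control called 451 genes (200 up, 251 down). Smaller values of Igsf23 (1.22, SE 0.57, adjusted p = 0.314), Fam167b (1.17, SE 0.57, 0.350), Treml2 (1.13, SE 0.53, 0.314), Rps14 (0.10, SE 0.04, 0.215) and Unc13a (-0.14, SE 0.04, 0.0524) no longer passed. Apoe (0.21, SE 0.07, 0.132), Rpl15-ps2 (-2.41, SE 0.84, 0.159), Igf1 (0.34, SE 0.10, 0.0923) and Cyp4a12b (1.52, SE 0.45, 0.0699) did not pass either; they moved by less than 1 SE, and their SE widened. Scaling by library totals gave 191 up and 1142 down, 14.3% upward against 46.9% with TMM, and the rises of Rps15 (adjusted p = 0.114), Rps14 (0.129) and Ndufa8 (0.161) did not pass under it. DESeq2 called 1476 genes and limma-voom 1112.

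The genotype comparisons in induced and control mice used different libraries. Both called 484 genes, 201 upwards and 283 downwards, where independent lists would share 13.7 and 19.3, and 0 genes were called in opposite directions; 434 of the 484 were protein coding. Bdnf, Chac1, Pde10a, Scn4b, Prss41, Gpr15 and Guca1b were among them. The log2 fold changes of the comparisons had a Pearson r of 0.49 and a Spearman rho of 0.33 across genes. Calls lay unevenly along the genome. Of 273 windows of 10 Mb, 14 were enriched for calls in induced and 9 in control mice, and 5 in both: 0 to 10, 20 to 30 and 40 to 50 Mb of chromosome 17, the last holding Trem2, Treml2 and Guca1b, 170 to 180 Mb of chromosome 1 and 50 to 60 Mb of chromosome 6. On chromosome 17, 16.8% of 935 tested genes were called in induced and 13.8% in control mice. Windows enriched in either state held 10.9% of tested genes and 34.5% of the 484 shared calls. Outside them, 823 genes were called in induced and 841 in control mice.

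**Figure D3:**
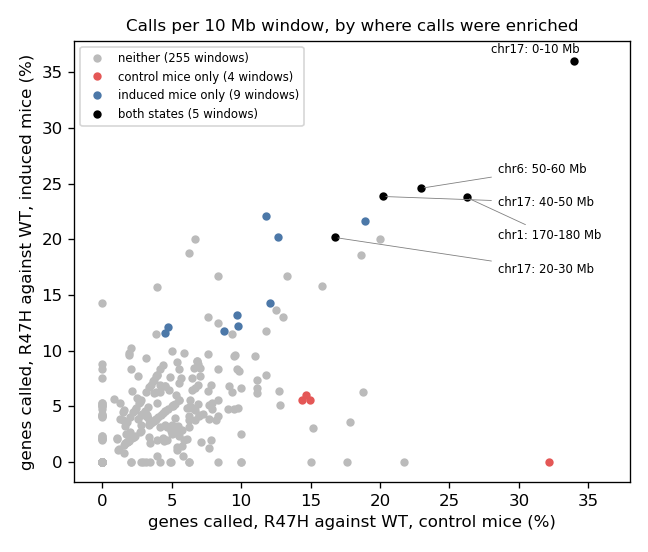
Percent of tested genes called in R47H against WT in control mice (x axis) and in induced mice (y axis), 1 point per 10 Mb window; colours mark windows enriched for calls in neither state (255), in control mice only (4), in induced mice only (9) and in both (5, labelled). The window at 0 to 10 Mb of chromosome 17 had 34% of its genes called in control and 36% in induced mice.

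**Figure D4:**
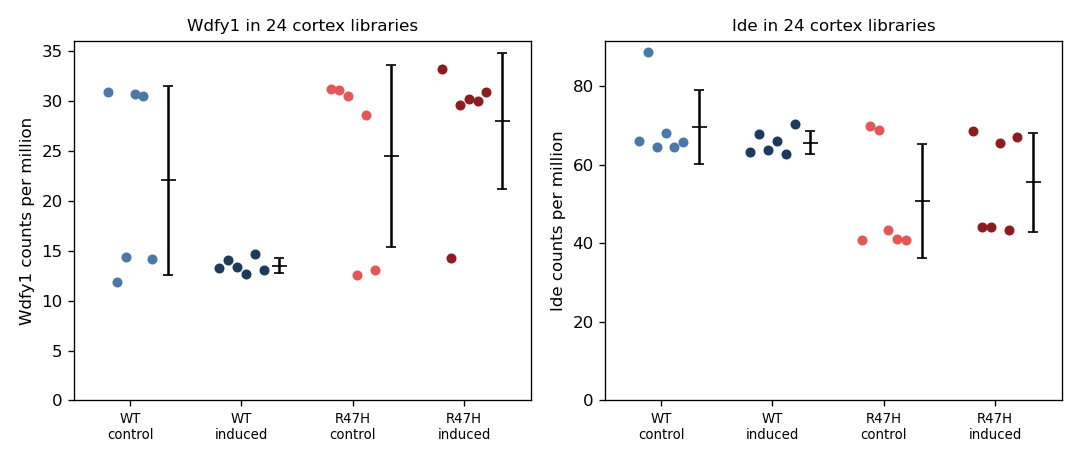
Wdfy1 (left) and Ide (right) in CPM (y axis) for each of the 24 libraries by group; points are libraries and the bars are mean ± SD (n = 6). Wdfy1 lay at 11.9 to 14.7 CPM in 12 libraries and 28.6 to 33.2 in 12, and Ide at 40.8 to 44.3 CPM in 7 libraries and 62.8 to 88.8 in 17.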

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

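In this part, the tests of the interferon pattern without WT_induced replicate 6, of blood left in the dissection and of its red cell rank, the interval of the correlation with the rRNA-like share, that correlation within WT_induced and the comparison by sex-linked genes were chosen only after the result was seen. So was the comparison of the scores of tamoxifen-treated R47H mice with those of their controls.

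A library was taken to stand apart when its gap to the nearest library of its group, divided by the range of the 6, exceeded the 95% critical value of Dixon's test for 6 values. Of 168 groups of 6 libraries (42 measures), 16 did so, and 10 of the 16 were WT_induced replicate 6. Chance gives about 1 in 20 independent groups. The lists screened were those that camera called in these same data, and the measures overlap, so the 16 cannot be judged against that rate. That library was the highest of its group in Tyrobp (gap ratio 0.726), Aif1 (0.791), Csf1r (0.710) and Gfap (0.728), and in the mean log2 CPM of the lists TREM2 signalling partners (0.767), pan-microglial and myeloid (0.843), disease-associated microglia (0.725), antigen presentation (0.708), inflammatory cytokines and receptors (0.719) and lysosome (0.628). R47H_induced replicate 4 was the highest of its group in Tmem119 (0.654) and the astrocyte list (0.760). R47H_induced replicate 5 was the highest in the ribosomal protein (0.667) and meningeal fibroblast lists (0.643), WT_induced replicate 4 in the inhibitory neuron list (0.761) and WT_control replicate 2 in the red blood cell list (0.640).

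Median log2 differences of the inductions, R47H minus WT, passed camera for 17 lists, none of them with an estimated correlation (adjusted p = 0.272 to 0.532). Immune and glial lists had lower induction values in R47H than in WT mice: antigen presentation (-1.41), interferon response (-0.94), inflammatory cytokines and receptors (-0.46), pan-microglial and myeloid (-0.40), reactive astrocyte (-0.38), TREM2 signalling partners (-0.19), homeostatic microglia (-0.15), disease-associated microglia (-0.14), lysosome (-0.081) and astrocyte (-0.076). Meningeal fibroblast (-0.20), thalamus (-0.12), endothelial (-0.12) and inhibitory neuron lists (-0.084) were lower too. Immediate early genes (0.47), circadian clock (0.097) and cholesterol synthesis (0.034) were higher. Without WT_induced replicate 6 antigen presentation was at -0.50 and interferon response at -0.31. The inflammatory, TREM2 signalling partners and homeostatic microglia lists then lost their calls.

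Interferon response and antigen presentation genes were highest in WT_induced, and most so in replicate 6, whose mean log2 CPM was 3.32 and 4.68 against 1.18 ± 0.45 and 1.87 ± 0.48 (SD, n = 5) in the rest of its group. Whole blood left in the dissection was argued against by the red blood cell list, where replicate 6 ranked 22 of 24 libraries from the top, although its 20 blood leukocyte genes summed to 35.3 CPM against 6.31 to 8.98 CPM in the other 23, with 379 counts of Ccr2 and 173 of Plac8; leukocytes without red cells stay open. The rRNA-like share stays open: its r with the interferon score was -0.309 over the 18 libraries of the other groups (permutation p = 0.213, 95% interval -0.678 to 0.185; rho -0.203, p = 0.416; r 0.0373 without the 2 farthest libraries) but 0.878 within WT_induced (n = 6, exact permutation p = 0.0125; 0.782 without replicate 6), so its effect cannot be told apart from others there. A rule set beforehand, an r over those 18 libraries that was not positive, was met and would have counted against the share. That rule was set aside for the interval, chosen afterwards, which reaches positive values. Whether 1 outlying library makes the pattern cannot be told apart from a response of the group, since without replicate 6 the interferon score difference from WT_control was 0.244 of 0.601 and that of antigen presentation 0.280 of 0.748. A response to tamoxifen shared by both lines was argued against by the R47H_induced mice, which received it too. The interferon score was 0.610 ± 0.191 in R47H_induced and 0.617 ± 0.221 in R47H_control (SD, n = 6). The antigen presentation score was 1.69 ± 0.094 in R47H_induced and 1.84 ± 0.096 in R47H_control. A response to the induced WT form, or to tamoxifen in the WT line alone, stays open. So do an infection or inflammation of single mice and sex. In WT_induced the 3 libraries with Xist above the Y-linked genes were replicates 1, 4 and 6. Their interferon score exceeded that of the other 3 by 1.29 (exact permutation p = 0.1, the smallest 3 against 3 allows). The same difference was -0.29 in R47H_induced (exact permutation p = 0.1) and 0.19 in R47H_control (exact permutation p = 0.4). In WT_control it was -0.0066 (exact permutation p = 1).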

How the results depend on the processing

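Settings named here as covariates for the rRNA-like share or the choroid plexus list and list tests without WT_induced replicate 6 were chosen after seeing the data. The comparisons R47H against WT, induced and R47H against WT, control kept counts within 1.5 times of 1142 and 1129, from 875 to 1058 and from 823 to 1132 with 1 library left out, except at a threshold of 0.1 (1853 and 1953, by construction) and, in control mice, with the rRNA-like share as a covariate (451; the cause was not tested). For induction in WT mice, induction in R47H mice and the difference of induction between R47H and WT, where edgeR called 0, DESeq2 called 2, 2 and 3 genes, and edgeR on 12 libraries called 1 in R47H mice. Leaving out 1 library gave 0 to 1 (WT_control replicate 2), 0 to 2 (R47H_induced replicate 3) and 0 to 1 calls (WT_control replicate 2 and WT_induced replicates 2 and 3). The Trem2 log2 fold change, R47H against WT, control passed with the choroid plexus covariate (0.37), voom sample weights (0.29) and 12 libraries (0.30) but not with the rRNA-like share (0.25, adjusted p = 0.334), and ranged from 0.26 to 0.35 with 1 library left out, passing without R47H_control replicate 2 (0.35, adjusted p = 0.0473). For gene list tests, R47H against WT, control, 8 lists were called and 14 with library totals or the oligodendrocyte covariate; for gene list tests, R47H against WT, induced, 12 and, without WT_induced replicate 6, 7 (5 of the 12 and 2 others). With an estimated correlation 0 lists passed in each of the 5 comparisons, by the wider variance it assigns. The cause of the other moves was not tested. Over the remaining values 51 lost and 16 gained the threshold, while 1623 had the same status, passing in both fits or in neither. With 1 library left out 45 lost it, 4 gained it and 1823 had the same status. Of called values 0 reversed. Of the 3698 values compared 49 had another sign while passing under neither setting. A further 6 had no adjusted p from DESeq2. No paired analysis was possible because replicate numbers were assigned in accession order. Depth limits low genes: Cst7 and Clec7a, with 211, 183 and 42 counts over 24 libraries, could not be tested, and the ratios of Klk1b22, Guca1b and Trim43b rest on 0 or 1 count in WT mice.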

Other observations

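In this part, the averaged contrasts, the test of chromosome segments that differ between the 2 lines, the removal of overlapping pairs and the comparison of splits with sex-linked genes and the rRNA-like share were chosen only after the result was seen.

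Several genes near 134 Mb of chromosome 4 differed between the genotypes in induced mice. Stmn1, encoding stathmin, was at -0.54, the cell cycle regulator Sfn (133600556 to 133602168) at -1.15, the kinase Map3k6 at -0.95, the chromatin protein Hmgn2 at -0.73 and the selenoprotein Sepn1 at 0.37 (log2, R47H against WT, edgeR adjusted p from 0.000178 to 0.00148). In control mice the same genes had log2 values of -0.16, -0.41, -0.40, -0.17 and 0.12, of the same sign, with adjusted p from 0.111 to 0.441. The difference of inductions of Stmn1 was -0.37 (SE 0.12) and did not pass (adjusted p = 0.530), so a difference between the states is not shown. These genes were picked for the lowest p in the induction in R47H mice, which uses the same R47H_induced libraries. Whether a chromosome segment that holds them differs between the mice was not tested.

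Averaged over both genotypes, induction called 0 genes in edgeR (913 at an unadjusted p below 0.05). Stab1, a scavenger receptor of border-associated macrophages and sinusoidal endothelium (chromosome 14, 31139013 to 31168641), had the lowest p, at -0.31 (SE 0.06, adjusted p = 0.117), with -0.30 (SE 0.08) in WT and -0.32 (SE 0.08) in R47H mice. Mrc1, of the same list, was at -0.02 (SE 0.14) in WT and -0.04 (SE 0.14) in R47H mice, where the list as a whole was called downwards by camera at the preset correlation (2 of 10 members positive, adjusted p = 0.00527; 0.274 with an estimated correlation). The averaged genotype difference called 2724 genes, 1308 up and 1416 down. Among lists called in no comparison of all 24 libraries, the lowest adjusted p was 0.0838 for the Trem family and its neighbours and for lipid efflux genes (control mice), 0.0911 for oestrogen receptor targets and 0.107 for oligodendrocyte genes (induced mice), 0.308 for hippocampus and 0.828 for blood leukocyte genes (induction in WT mice), of which 4 of 20 passed the expression filter. Median, mean and test differed in sign for 25 results, none of them called; the blood leukocyte list did so in each of the 5 comparisons, the oxidative phosphorylation list in 3 and the hippocampus list in 3.

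Other splits of the 12 libraries into 6 and 6 were drawn 100 times per comparison, the real one included, and for the difference of inductions 60 splits of all 24. For R47H against WT 1 of 100 splits, the real one, gave as many calls in induced mice (826, highest other 17) and 1 of 100 in control mice (1001, highest other 146). This argues against a random grouping of the libraries as the source of these counts. It does not tell the TREM2 form from other differences between the lines. For induction in R47H mice a random grouping stays open (real 1, 9 of 100, highest other 4). For induction in WT mice (100 of 100 splits, highest other 20) and the difference of inductions (60 of 60, highest other 2) the real split gave 0 calls, which any split reaches, so the splits say nothing there. The splits with 146 and 17 calls parted all 12 libraries by their sex-linked genes, which is a structure of the samples other than the groups. The split with 20 calls in the WT libraries followed neither the groups nor the sex-linked genes (6 of 12 libraries for each). Its sides were 3.67 points apart in the rRNA-like share, but a split with sides 4.90 points apart gave 0 calls. Whether a further structure lies behind the 20 calls was not tested.

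Genes that differ between the genotypes were clustered in windows of the genome, 9 of 273 in control mice. Expression level was argued against, since shuffling the calls among genes of similar expression gave at most 1 enriched window in 200 shuffles, and the rRNA-like share too, since 8 windows were enriched with it as a covariate. How many of the 8 were among the 9 was not counted. With that covariate the calls inside the 9 windows went from 184 to 103, and those outside from 945 to 348. Chromosome segments that differ between the 2 lines remain a candidate explanation, as 5 windows were enriched in both control and induced mice where independent windows would share 0.462 (exact hypergeometric p = 1.85e-05). Control mice had received no tamoxifen, so the 9 windows enriched there do not need induction by it. Whether the TREM2 form was expressed without tamoxifen was not tested. The TREM2 form and the line that carries it differ together in this design, so an effect of the form on these genes was not tested and stays open.

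Across the 24 libraries, 28 of 11675 autosomal genes above 5 CPM lay at 2 separate levels, and 21 of them were called in neither genotype comparison. Besides Wdfy1 and Ide, which encodes the insulin-degrading enzyme, Serpina3n, a marker of reactive astrocytes, was at 7.25 to 8.66 CPM in 4 libraries and 33.3 to 75.2 CPM in 20. A library-wide factor was argued against, since 2.47% of 364 pairs on different chromosomes parted the libraries the same way. Noise around 1 level as the source of most of the 28 genes was argued against, since 20 simulated tables held at most 3 such genes. The bound set beforehand, under 0.1 of the 28 in every table, was missed, so noise stays open for a few of them. Segregating chromosome segments could not be judged, since 0% of 1 usable pair within 5 Mb parted the libraries the same way where 5 pairs were needed. Both levels of 9 of these genes occurred in all 4 groups, and no biological explanation was tested.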
